A study of Rattus norvegicus with 6 samples.

How the data were processed

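Gene expression was measured in 6 RNA samples of rat fibroblasts on the Affymetrix rat genome oligonucleotide array (chip A of its set). 208F is an immortal, non-transformed line and FE8 is its derivative transformed by the HRAS oncogene. The samples were untreated 208F (n = 1), untreated FE8 (n = 1), 208F given 0.3 µM 5-aza-2'-deoxycytidine for 96 h (n = 2) and FE8 given the same dose for the same time (n = 2). The drug is a cytidine analogue that blocks DNA methyltransferases. Per the labels, RNA was extracted with TRIzol, cleaned on RNeasy columns, checked on a Bioanalyzer and turned into biotinylated cRNA. The labels do not state whether the duplicates came from separate cultures, so every p value of a probe set here measures the spread between these samples, which may be technical.

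The deposited values are signal intensity per probe set on a linear scale, rounded to whole numbers, and the submitters' processing notes name MAS5 without a version or settings. Column means lay between 1258 and 1389.5, so the table was taken as already scaled between arrays. The table held 4847 probe sets, a subset of the array chosen by a filter that is not stated. Of these, 29 were control probe sets and 4818 were tested. Precision was limited by the number of arrays.

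Probe sets were named from a table of rat genes of assembly GRCr8, which was used for names only. One gene was listed for 3956 probe sets (2890 genes), several genes for 207 and none for 655, and 3942 were matched by gene identifier. A suffix marking a probe set that may be shared between transcripts (_s, _f, _i or _r) stood on 956 probe sets. Hras was not among the measured genes.

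Run settings of each array were read for batches. Both untreated arrays were run in the same session on chips of lot 1. The treated arrays were run in a later session, 208F replicate 1 on its own day and lot 2, the other 3 on the same day and lot 3. Drug and session therefore cannot be told apart, and no fit with session as a term can be had. The untreated line comparison lies within lot 1. For the treated line comparison the value within lot 3 is the fit without 208F treated replicate 1. The difference between the drug effects cancels the session only if the session acted alike on the log scale in both lines. FE8 treated replicate 2 had a settings record of a second scan but only 1 set of values.

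Signals were transformed as log2(value + 64), where 64 is the 10th percentile of all tested values, with no further normalization. Where a signal lies near or below 64, the size of a log2 difference is held down by this pseudocount, and sizes and ranks of such genes depend on it. A model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), leaving 2 residual and 9.02 prior degrees of freedom. The untreated arrays had no replicate and were assumed to vary like the treated duplicates. Errors given as ± are standard errors on the log2 scale from this fit. Tests were 2-sided moderated tests of limma, with Benjamini-Hochberg adjustment over 4818 probe sets within each comparison and a threshold of 0.05. The comparisons were FE8 against 208F without and with the drug, the drug effect in 208F, in FE8 and averaged over the lines, and the difference between the drug effects.

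Named genes were the 12 with the largest rise and the 12 with the largest fall past the threshold in each comparison, with 1 probe set per gene (smallest p). With fewer than 10 calls, the 12 genes with the smallest unadjusted p were named. For the class lower in FE8 and raised by the drug, the 12 with the largest sum of absolute changes were named. Up to 4 members per list and direction could be named in order of absolute change, and clusterin was always named. Among named genes with more than 1 probe set, another probe set moved the other way for 1 of 12 in the 208F drug effect, 1 of 16 in FE8 and 1 of 10 in the treated line comparison.

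For gene groups, 24 lists of 599 genes were fixed, covering RAS signalling, matrix and cytoskeleton, immune and stress responses, metabolism, imprinting and other cell types. A list was tested with at least 4 measured genes, using the brightest probe set of each gene, so a member's value can differ from that of the gene's named probe set. The test was camera in limma with a preset correlation of 0.01, adjusted over 22 lists within a comparison. With that preset, camera takes its error from the spread of statistics among genes and not from the spread between arrays. A small camera p therefore does not measure how well a list difference would repeat in other samples. Each list was also tested with a correlation estimated from the residuals, and with fry, which asks whether the members move on balance in 1 direction without comparing them with other genes. The test with an estimated correlation has only the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. For epithelial genes in the FE8 drug effect, the camera p went from 5e-07 to 0.035 although the estimated correlation was -0.02. A list that fails this test is therefore not shown to owe its call to correlated members. The groups, comparisons, tests, lists and naming rule, and all alternatives not marked as added later, were chosen before the data were examined.

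A second rule without a test counted probe sets at least 2-fold changed, on the signal plus 64, in both treated arrays against the untreated array of the line. Counts for genes lower in FE8 and raised by the drug were set beside 100 simulated data sets without any effect in which the comparisons shared the FE8 control, and beside the number expected if the calls of the comparisons were independent. The fit was tested on simulated data of 4818 probe sets with 100 changed 2-fold and 100 changed 4-fold. It recovered 35.0% and 96.0% for the drug effect in 208F, 28.0% and 94.0% in FE8, 87.0% and 100.0% for the averaged effect and 13.0% and 68.0% for the difference. For the lines it recovered 22.0% and 88.0% without the drug and 48.0% and 99.0% with it. Beside these, there were 15 false calls for the drug effect in 208F, 7 in FE8, 9 averaged and 11 for the difference. For the lines there were 9 without the drug and 8 with it. In that simulation false calls made up a larger share of all calls than the threshold allows in every comparison but the averaged effect. In 100 simulated data sets without effects, 1 had any list called in the untreated line comparison. Genes varied independently there, while the estimated correlation of interferon genes in the data was 0.52. The simulation therefore does not give the rate of false list calls in these data.

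The alternatives were a pseudocount of 1 or of the 30th percentile (190), leaving out the lowest 30% of probe sets, quantile normalization, median centring, no intensity trend, 1 probe set per gene, leaving out each treated replicate, a term for replicate number, folds of 1.5 and 3, and for lists an estimated correlation or fry. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.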

Results

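The data collected were 6 arrays of rat fibroblasts with signals for 4818 tested probe sets. The study's design asks which genes change after demethylation with 5-aza-2'-deoxycytidine (the drug) in immortal 208F cells and in HRAS-transformed FE8 cells. There was 1 untreated array per line and 2 treated arrays per line. Median signals were 354 for untreated 208F, 374 and 422 for treated 208F, 356 for untreated FE8, and 406 and 382 for treated FE8. Treated duplicates correlated across probe sets with r = 0.959 in 208F and 0.969 in FE8, and the untreated arrays of the lines correlated with r = 0.904.

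Ratios of 5' to 3' signal, a sign of RNA quality, differed between arrays. For beta-actin the ratio was 0.824 in untreated 208F, 0.529 and 0.456 in treated 208F, 0.351 in untreated FE8, and 0.405 and 0.384 in treated FE8. For GAPDH it was 0.916, 1.132 and 1.010 in 208F in the same order, and 0.691, 1.126 and 1.073 in FE8. Both untreated arrays belonged to a run session of their own, so every drug effect below is also a difference between sessions, and the drug and the session cannot be told apart.

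The first comparison asked which genes differed between the lines, in untreated FE8 (n = 1) against untreated 208F (n = 1). FE8 was the only transformed line and Hras was not measured, so transformation cannot be told apart from other differences between the lines. 3 secreted matrix metalloproteinases, enzymes that degrade extracellular matrix, were far higher in FE8, while others were not. The log2 difference was 7.37 ± 0.35 for the stromelysin Mmp10 (probe set M65253_at, adjusted p = 1.6e-06), with signals of 12849 and 14, and 5.65 ± 0.32 for both Mmp3 and the collagenase Mmp13. Among the genes lower in FE8, the difference was -6.18 ± 0.38 for Tagln, which encodes the actin-binding protein transgelin, -5.83 ± 0.32 for Col1a1, a chain of type I collagen, and -5.37 ± 0.41 for Acta2, smooth muscle actin.

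Of 4818 probe sets, 149 were higher in FE8 and 136 were lower, 285 in all. Among other named genes, Ptprn, a phosphatase-like protein of secretory granules, was higher by 5.08 ± 0.32, the sulfotransferase Sult1b1 by 4.36 ± 0.55 and the stearoyl-CoA desaturase Scd by 4.15 ± 0.48. Serpinb2, an inhibitor of plasminogen activators, was higher by 3.72 ± 0.40, and the further named genes Plcd4, Cyp3a9, Slc6a15, Ocm and Psmb8 lay between 3.51 and 4.26. On the lower side, the myosin light chain Myl9 was at -5.39 ± 0.41, the carbonic anhydrase Car3 at -5.13 ± 0.40, fibulin Fbln5 at -4.17 ± 0.40 and the growth factor Tgfb3 at -4.04 ± 0.39. Cryab, Cald1, Fn1, Mmp2 and Gas6 lay between -3.88 and -3.54. The second probe set of Scd differed by 0.02.

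Among gene lists, 9 of 19 measured extracellular matrix genes were lower in FE8, 1 was higher and 9 did not pass the test, with 14 lower and 1 higher adjusted over the list alone. Examples were Col1a1 at -6.84 ± 0.48 by its brightest probe set, Fbln5, and Col3a1 at -3.49 ± 0.48, while the lysyl oxidase-like Loxl1 was higher by 1.93 ± 0.30. The list was called (median -1.43, adjusted p = 1.6e-13), but not in the test with an estimated correlation (adjusted p = 0.45), which few lists could pass. Of 12 actin and contractile genes, 6 were lower, 1 was higher and 5 did not pass (9 and 1 adjusted over the list alone, median -2.18, adjusted p = 1.2e-12, and adjusted p = 0.45 with an estimated correlation). The 208F control that these differences rest on had the highest beta-actin ratio of 5' to 3' signal, 0.824.

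Of 16 secreted proteases and inhibitors, 5 were higher, 2 were lower and 9 did not pass (7 and 2 adjusted over the list alone, median 0.21, adjusted p = 0.011, and adjusted p = 0.45 with an estimated correlation). Beside the metalloproteinases named above, the plasminogen activator Plat was higher by 2.50 ± 0.51, and Mmp2, a gelatinase, was lower by -3.54 ± 0.37. Of 13 cholesterol synthesis genes, 5 were higher and 8 did not pass (9 higher adjusted over the list alone, median 1.08, adjusted p = 4.4e-07, and adjusted p = 0.45 with an estimated correlation). They included squalene epoxidase Sqle at 2.17 ± 0.38 and the sterol oxidase Msmo1 at 1.46 ± 0.35. Of 11 ER stress genes, 2 were higher and 9 did not pass (5 higher adjusted over the list alone, median 0.78, adjusted p = 0.00017, and adjusted p = 0.45 with an estimated correlation), the 2 being the pseudokinase Trib3 at 3.39 ± 0.42 and the transcription factor Ddit3 at 3.27 ± 0.31.

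RAS-MAPK output genes were not called as a list (median 0.21, adjusted p = 0.057, and adjusted p = 0.53 with an estimated correlation). Of its 18 measured members, 5 were higher, none was lower and 13 did not pass, with 6 higher and 1 lower adjusted over the list alone. They included Fosl1, an AP-1 subunit, at 3.22 ± 0.38, the ERK phosphatase Dusp6 at 3.13 ± 0.33, osteopontin Spp1 at 2.65 ± 0.40, and the phosphatase Dusp5 at 2.24 ± 0.31. MHC class I genes were called higher with 1 of 11 members past the threshold, the immunoproteasome subunit Psmb8 at 3.51 ± 0.36 (1 adjusted over the list alone, median 0.61, adjusted p = 0.029, and adjusted p = 0.45 with an estimated correlation). Of 6 genes reported as silenced by RAS, 2 were lower and 4 did not pass (4 lower adjusted over the list alone, median -1.26, adjusted p = 0.0014, and adjusted p = 0.45 with an estimated correlation). That list was drawn from work on this kind of cell and holds clusterin, so it is not independent evidence of its direction.

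With fry, 2 lists were called, the actin and contractile genes and the secreted proteases (adjusted p = 0.047 for both). Neither arm of this comparison had a replicate, and the count fell to 109 without FE8 treated replicate 1 and 113 without replicate 2, and rose to 541 and 536 without 208F treated replicates 1 and 2.

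The lines were next compared under the drug, FE8 (n = 2) against 208F (n = 2), a comparison that shares no array with the untreated one. The same 3 metalloproteinases were higher in FE8, Mmp10 by 7.41 ± 0.25 (adjusted p = 3.6e-08), Mmp3 by 5.29 ± 0.23 and Mmp13 by 5.12 ± 0.22. Rsad2, an antiviral gene induced by interferon, was higher by 4.33 ± 0.31. Col1a1 was lower at -4.94 ± 0.25 and Tagln at -4.38 ± 0.27. H19, an imprinted non-coding RNA, was at -4.16 ± 0.31 with signals of 45 and 24 in FE8 and 1830 and 1560 in 208F.

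There were 341 probe sets past the threshold, 165 higher in FE8 and 176 lower, and each named gene separated all 4 treated arrays by line. Other named genes that were higher were the homeobox gene Alx1 at 3.74 ± 0.33, the cadherin Cdh17 at 3.67 ± 0.32, Serpinb2, the fatty acid binding protein Fabp4, Mal, the water channel Aqp1, tyrosine hydroxylase Th and the chemokine Cxcl10, the last at 2.92 ± 0.25. Those lower were Car3 at -3.86 ± 0.28, the small heat shock protein Cryab at -3.58 ± 0.26, Fbln5, Col5a2, Ccn1, Acta2, Tgfb3 and Ddah1, the last at -3.07 ± 0.31. Sparc, a matrix glycoprotein, was lower by -3.47 ± 0.30, with 3 of its 4 probe sets called lower, while the brightest stood at 0.21 ± 0.28.

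Of 12 interferon response genes, 7 were higher in treated FE8 and 5 did not pass (9 adjusted over the list alone, median 1.38, adjusted p = 4e-10, and adjusted p = 0.34 with an estimated correlation). Besides Rsad2 and Cxcl10 these included the transcription factor Irf7 at 2.11 ± 0.34 and the GTPase Mx2 at 1.87 ± 0.48. Of 18 RAS-MAPK output genes, 8 were higher and 10 did not pass (9 higher and 1 lower adjusted over the list alone, median 0.68, adjusted p = 3.8e-06, and adjusted p = 0.34 with an estimated correlation). Of 16 secreted proteases and inhibitors, 5 were higher, 2 lower and 9 did not pass (12 and 3 adjusted over the list alone, median 0.84, adjusted p = 8.4e-07, and adjusted p = 0.33 with an estimated correlation).

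Among extracellular matrix genes, 9 of 19 were lower and 10 did not pass (13 adjusted over the list alone, median -0.93, adjusted p = 4.4e-12, and adjusted p = 0.34 with an estimated correlation). Of 12 actin and contractile genes, 8 were lower and 4 did not pass (8 adjusted over the list alone, median -1.95, adjusted p = 1.2e-10, and adjusted p = 0.33 with an estimated correlation). MHC class I genes were called higher (2 of 11 past the threshold, 6 adjusted over the list alone, median 0.72, adjusted p = 5.2e-05, and adjusted p = 0.34 with an estimated correlation). Muscle differentiation genes were called lower (2 of 15, Myod1 at -2.30 ± 0.28 and Acta1 at -1.26 ± 0.33, 3 adjusted over the list alone, median -0.51, adjusted p = 0.0047, and adjusted p = 0.34 with an estimated correlation), a call lost without 208F treated replicate 2 (adjusted p = 0.065). Genes reported as silenced by RAS were lower (2 of 6, 4 adjusted over the list alone, median -0.65, adjusted p = 0.0051, and adjusted p = 0.36 with an estimated correlation), again not as independent evidence. Cholesterol synthesis genes had none of 13 past the threshold (0 adjusted over the list alone), a median of -0.11 and adjusted p = 0.65.

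Within lot 3, without 208F treated replicate 1, 491 probe sets passed, and medians of the matrix, actin, interferon and protease lists were -0.81, -1.83, 1.32 and 0.79. The count was 530 without 208F treated replicate 2, and 136 and 96 without FE8 treated replicates 1 and 2.

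**Figure D1:**
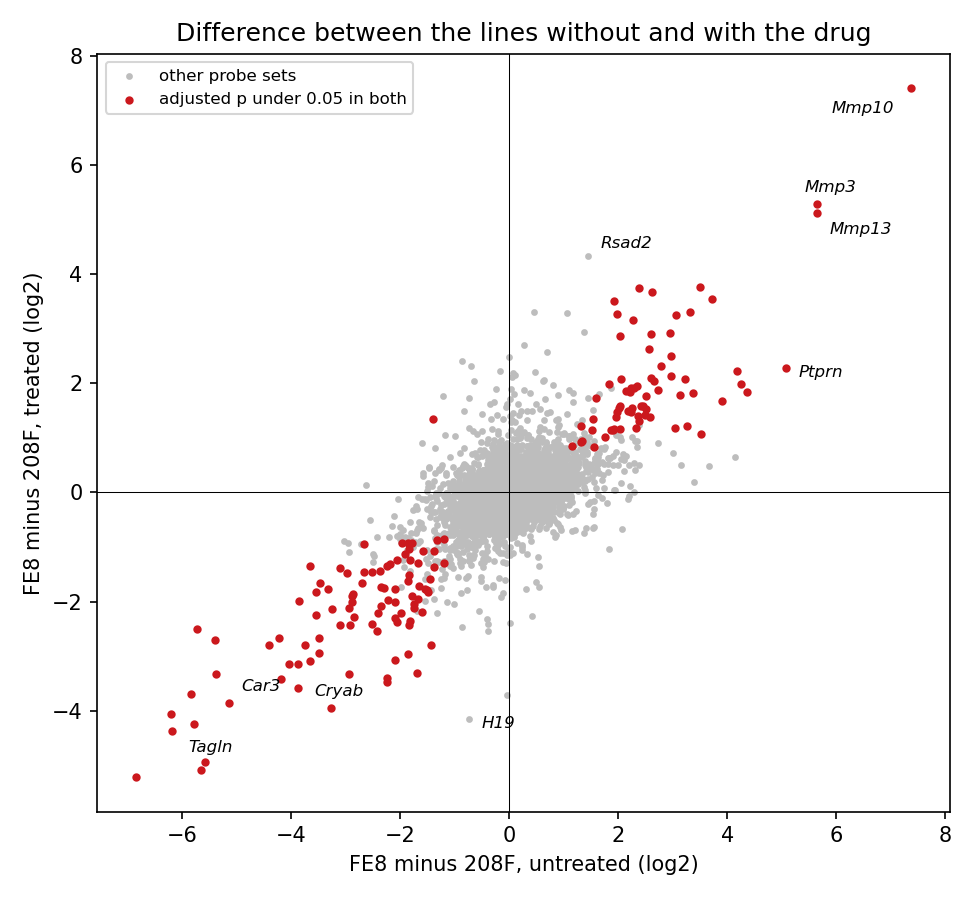
Log2 difference of FE8 minus 208F for each of 4818 probe sets, untreated (x axis) against treated (y axis); red points passed the threshold in both comparisons. Of the red points, 69 were higher in FE8 in both, 92 were lower in both and 1, Fabp5, lay in opposite directions.

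The line differences without and with the drug correlated across probe sets with Pearson's r = 0.659 and Spearman's rho = 0.471, where probe sets are not independent replicates. In simulated data without effects, where arrays had independent errors, the correlation averaged -0.001. Both comparisons called 69 probe sets higher, against 5.1 for independent lists, and 92 lower, against 5.0. The sign was shared by 64.9% of all probe sets. The agreement of line effects was 0.565 without 208F treated replicate 1. The plot of line differences shows that Mmp10, Mmp3 and Mmp13 kept a like difference under the drug, and the exception Fabp5 was at -1.39 without the drug and 1.35 with it.

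The effect of the drug was then asked for in each line. In 208F (treated n = 2, untreated n = 1), the largest rise was in Chrna7, a subunit of the neuronal nicotinic acetylcholine receptor, by 5.18 ± 0.29 (probe set S53987_at, adjusted p = 4.2e-06), with signals of 3756 and 4627 against 53. The simple epithelial keratin Krt8 rose by 3.79 ± 0.27, the surface glycoprotein Cd24 by 3.79 ± 0.33, H19 by 3.62 ± 0.38 and Cdkn1a, an inhibitor of cyclin-dependent kinases, by 3.42 ± 0.32. Myl9 fell, at -2.83 ± 0.36, as did the collagen chain Col5a1 at -2.51 ± 0.33 and Acta2 at -2.48 ± 0.36. The second probe set of Chrna7 stood at 0.36.

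In total 250 probe sets passed in 208F, 173 higher and 77 lower, with every named gene moving the same way in both treated arrays. The other named rises were in the calcium-binding protein Ocm (4.45 ± 0.29), Ptgr1, Spint2, the lipid droplet protein Plin2 (3.34 ± 0.27), the intermediate filament desmin (Des, 3.33 ± 0.54), the drug efflux pump Abcb1b (3.27 ± 0.26) and Trib3. Other named falls were in Slc4a2, Col3a1, the homeobox gene Meox2, Myl6b, Cyp51, the DNA polymerase subunit Pold1 (-1.99 ± 0.45), Tmpo, Nrp1 and Fbln5. The second probe set of Plin2 stood at 0.25, and that of Slc4a2 at 0.12. Of 5 Cyp51 probe sets, all lower (-2.01 to -0.26), 1 passed, as did 1 of 4 for Tmpo (-1.94 to -0.50). Without FE8 treated replicate 1 or 2, the falls of Myl6b (adjusted p = 0.061 and 0.059), Pold1 (0.064 and 0.065), Tmpo (0.054 and 0.054), Nrp1 (0.064 and 0.065) and Fbln5 (0.064 and 0.061) no longer passed. In those fits the error rests on the 208F duplicates alone. The Slc4a2 call was lost in 5 of the settings, among them quantile normalization (adjusted p = 0.088).

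Proliferation genes fell in 208F, 3 of 17 past the threshold and 14 not (9 adjusted over the list alone, median -0.75, adjusted p = 2.3e-08, and adjusted p = 0.32 with an estimated correlation). They were the helicase subunits Mcm7 at -1.45 ± 0.26 and Mcm6 at -1.20 ± 0.28, and the cell cycle kinase Cdk1 at -1.42 ± 0.28. Of 6 p53 targets, 3 rose and 3 did not pass (3 adjusted over the list alone, median 0.91, adjusted p = 0.0005, and adjusted p = 0.32 with an estimated correlation), namely Cdkn1a, Gadd45a at 1.70 ± 0.29 and the p53 ligase Mdm2 at 1.31 ± 0.26. Of 7 epithelial genes, 3 rose (3 adjusted over the list alone, median 0.90, adjusted p = 0.0002, and adjusted p = 0.32 with an estimated correlation), being Krt8, Spint2 and Krt18. Muscle differentiation genes rose with 3 of 15 (3 adjusted over the list alone, median 0.65, adjusted p = 0.0019, and adjusted p = 0.32 with an estimated correlation), including Des and the myogenic factor Myod1 at 1.99 ± 0.35.

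Cholesterol synthesis genes fell in 208F with 3 of 13 past the threshold, Acat2 at -1.71 ± 0.30, Fdps at -1.49 ± 0.28 and Msmo1 at -1.39 ± 0.30 (7 adjusted over the list alone, median -0.90, adjusted p = 6.6e-08, and adjusted p = 0.32 with an estimated correlation). Extracellular matrix genes fell with 6 of 19 lower and 1 higher (9 and 2 adjusted over the list alone, median -0.69, adjusted p = 1.9e-06, and adjusted p = 0.32 with an estimated correlation), and actin and contractile genes with 5 of 12 lower (6 lower and 1 higher adjusted over the list alone, median -0.76, adjusted p = 0.00038, and adjusted p = 0.32 with an estimated correlation). The beta-actin ratio of 5' to 3' signal moved with these groups, from 0.824 to 0.529 and 0.456. The GAPDH ratio moved the other way, from 0.916 to 1.132 and 1.010. RAS-MAPK output genes were called higher with 3 of 18 (8 adjusted over the list alone, median 0.60, adjusted p = 0.0005, and adjusted p = 0.32 with an estimated correlation), and cytokines and chemokines with 2 of 13, Ccl2 and Il33 (2 adjusted over the list alone, median 0.57, adjusted p = 0.013, and adjusted p = 0.32 with an estimated correlation). Proteases were called higher with 2 of 16, the plasminogen activator Plau and the cathepsin Ctsl (3 adjusted over the list alone, median 0.43, adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation). Interferon genes were called higher with 1 of 12, Rsad2 (2 adjusted over the list alone, median 0.68, adjusted p = 0.039, and adjusted p = 0.61 with an estimated correlation), and the call was lost without 208F treated replicate 2 (adjusted p = 0.054).

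The 208F count was 663 without 208F treated replicate 1, 416 without replicate 2, 75 and 78 without FE8 treated replicates 1 and 2, and 165 after quantile normalization. By fry no list was called, with the smallest adjusted p at 0.1.

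In FE8 (treated n = 2, untreated n = 1), Plin2 rose by 6.03 ± 0.27 (probe set rc_AA893280_at, adjusted p = 4.7e-07), from a signal of 38 to 6483 and 6738. Rsad2 rose by 5.56 ± 0.38, the fatty acid binding protein Fabp5 by 5.28 ± 0.31, Cdkn1a by 4.65 ± 0.39, Krt8 by 4.37 ± 0.27 and Chrna7 by 4.36 ± 0.29. The largest falls were in Scd at -3.47 ± 0.41, the isoprenoid enzyme Idi1 at -3.13 ± 0.31, Sult1b1 at -3.08 ± 0.48, Acat2 at -3.06 ± 0.30, the lanosterol demethylase Cyp51 at -3.03 ± 0.33 and Sqle at -3.01 ± 0.33. Untreated FE8 signals of Plin2 (38), Cdkn1a (43) and Fabp5 (8) lay below the pseudocount of 64, so the sizes of their rises, and their order, depend on it. The second probe set of Plin2 stood at 1.19, that of Chrna7 at 0.31, that of Scd at 0.01 and that of Idi1 at -0.93, and these did not pass.

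In FE8 393 probe sets passed, 244 higher and 149 lower, and the named genes moved alike in both treated arrays. Further named rises were in the tetraspanin Cd9 (4.03 ± 0.39), the meiotic synaptonemal complex gene Sycp3 (3.94 ± 0.62), Cd24, Irf7 (3.23 ± 0.41), natriuretic peptide Nppb and Ccl2. Further named falls were in Msmo1, Fdps, Prune2, Col5a2, Insig1 and squalene synthase Fdft1 (-2.09 ± 0.31). Without FE8 treated replicate 1 the calls of Sycp3 (adjusted p = 0.097), Prune2 (0.081) and Fdft1 (0.066) were lost, and without replicate 2 those of Sycp3 (0.086), Col5a2 (0.061) and Insig1 (0.077).

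Cholesterol synthesis genes fell in FE8, 10 of 13 past the threshold and 3 not (12 adjusted over the list alone, median -2.09, adjusted p = 2e-17, and adjusted p = 0.32 with an estimated correlation). Interferon response genes rose, 5 of 12 past the threshold (11 adjusted over the list alone, median 1.34, adjusted p = 3.5e-08, and adjusted p = 0.42 with an estimated correlation), with the kinase Eif2ak2 at 2.22 ± 0.45 after Rsad2 and Irf7. Proliferation genes fell with 5 of 17, among them the topoisomerase Top2a at -1.39 ± 0.28 (13 adjusted over the list alone, mean -0.86, adjusted p = 3.5e-08, and adjusted p = 0.32 with an estimated correlation). Epithelial genes rose with 5 of 7, including Spint2 at 2.69 ± 0.37 and the adhesion molecule Epcam at 2.15 ± 0.44 (5 adjusted over the list alone, median 1.68, adjusted p = 2.7e-06, and adjusted p = 0.32 with an estimated correlation). Of 6 p53 targets, 3 rose (3 adjusted over the list alone, median 0.98, adjusted p = 0.008, and adjusted p = 0.43 with an estimated correlation).

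RAS-MAPK output genes rose with 6 of 18, led by the immediate early gene Egr1 at 2.86 ± 0.29 and the phosphatase Dusp1 at 1.90 ± 0.30 (8 higher and 1 lower adjusted over the list alone, median 0.75, adjusted p = 5e-05, and adjusted p = 0.42 with an estimated correlation). Proteases rose with 5 of 16, Plau at 2.52 ± 0.35 and Mmp2 at 2.16 ± 0.32 among them (6 higher and 1 lower adjusted over the list alone, median 0.53, adjusted p = 0.00085, and adjusted p = 0.32 with an estimated correlation). ER stress genes were called lower, 4 of 11 below and 1 above (4 and 1 adjusted over the list alone, median -0.76, adjusted p = 0.0059, and adjusted p = 0.43 with an estimated correlation). Those below were the chaperone and disulfide isomerase genes Pdia4 (-1.70 ± 0.32), Pdia6, Hspa5 and Calr, and the transcription factor Atf3 was above at 1.56 ± 0.33. The ER stress call was lost without FE8 treated replicate 1 (adjusted p = 0.053). Extracellular matrix genes were called lower with 6 of 19 lower and 1 higher (9 and 1 adjusted over the list alone, median -0.47, adjusted p = 0.0092, and adjusted p = 0.55 with an estimated correlation), and the call was lost without FE8 treated replicate 2 (adjusted p = 0.053). Muscle differentiation genes were called higher with 1 of 15 (2 adjusted over the list alone, median 0.57, adjusted p = 0.013, and adjusted p = 0.42 with an estimated correlation).

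Further calls in FE8 were lost when 1 array was left out. Cytokines and chemokines (4 of 13 higher, 6 adjusted over the list alone, median 0.43, adjusted p = 0.018, and adjusted p = 0.42 with an estimated correlation) had an adjusted p of 0.05 without FE8 treated replicate 2 and no longer passed. MHC class I genes (1 of 11 higher, 4 adjusted over the list alone, median 0.56, adjusted p = 0.032, and adjusted p = 0.43 with an estimated correlation) had an adjusted p of 0.3 without it. The actin and contractile list was not called (1 of 12 higher, the caldesmon gene Cald1 at 1.90 ± 0.34, 1 adjusted over the list alone, median -0.14, adjusted p = 0.55). The untreated FE8 array had the lowest GAPDH ratio of 5' to 3' signal, 0.691, against 1.126 and 1.073 after treatment.

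The FE8 count was 76 and 77 without FE8 treated replicates 1 and 2, 783 and 779 without 208F treated replicates 1 and 2, and 258 after quantile normalization. By fry no list was called, with the smallest adjusted p at 0.053.

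Averaged over the lines (4 treated, 2 untreated arrays), Chrna7 rose by 4.77 ± 0.20, Plin2 by 4.69 ± 0.19, Cdkn1a by 4.28 ± 0.28, Rsad2 by 4.11 ± 0.27 and Krt8 by 4.08 ± 0.19. Cholesterol synthesis genes made up the largest falls, with Cyp51 at -2.52 ± 0.23, Acat2 at -2.39 ± 0.21, Msmo1 at -2.24 ± 0.21, Idi1 at -2.07 ± 0.22 and Fdps at -2.02 ± 0.20. Each of these genes moved the same way in all 4 treated arrays, with adjusted p between 1.2e-07 and 0.00015. The second probe sets of Chrna7 (0.33), Plin2 (0.72) and Idi1 (-0.44) did not pass.

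The averaged effect passed for 750 probe sets, 437 higher and 313 lower. The share of calls that rose in the effect averaged over lines was 58.3%, and 46.3% after median centring, so the balance of rises and falls turned with the scaling. The median of all drug effects was 0.113 in 208F, 0.082 in FE8 and 0.106 averaged, and -0.034, -0.041 and -0.036 after quantile normalization. Since camera compares a list with all other genes, its calls are relative to that shift. Other named rises were Fabp5, Cd24, Sycp3, Spint2, Cd9, Ptgr1 and the retinoic acid binding protein Crabp2, between 2.92 and 3.90. Other named falls were Tmpo, Col5a1, Sqle, Prune2, Sult1b1, Pold1 and Col3a1, between -1.92 and -1.76.

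Among lists in the averaged effect, 11 of 13 cholesterol synthesis genes fell (11 adjusted over the list alone, median -1.52, adjusted p = 4.6e-14, and adjusted p = 0.33 with an estimated correlation). Proliferation genes fell with 12 of 17 (13 adjusted over the list alone, median -0.87, adjusted p = 1e-09, and adjusted p = 0.33 with an estimated correlation). Matrix genes fell with 9 lower and 2 higher of 19 (9 and 2 adjusted over the list alone, median -0.57, adjusted p = 0.0001, and adjusted p = 0.38 with an estimated correlation), and actin and contractile genes with 4 lower and 1 higher of 12 (7 and 1 adjusted over the list alone, median -0.64, adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation). The beta-actin ratio of 5' to 3' signal fell with the drug in 208F (0.824 to 0.529 and 0.456) and not in FE8 (0.351 to 0.405 and 0.384). The GAPDH ratio rose in both lines, from 0.916 to 1.132 and 1.010 in 208F and from 0.691 to 1.126 and 1.073 in FE8.

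Genes rose in the averaged effect in 8 further lists of cell state and signalling. They were 5 of 7 epithelial genes (5 adjusted over the list alone, median 1.52, adjusted p = 2.5e-05, and adjusted p = 0.33 with an estimated correlation) and 6 of 12 interferon genes (9 adjusted over the list alone, median 1.07, adjusted p = 2.8e-05, and adjusted p = 0.38 with an estimated correlation). They were also 4 of 6 p53 targets (4 adjusted over the list alone, median 0.90, adjusted p = 0.0015, and adjusted p = 0.38 with an estimated correlation) and 10 of 18 RAS-MAPK output genes (11 higher and 1 lower adjusted over the list alone, median 0.77, adjusted p = 5.1e-05, and adjusted p = 0.38 with an estimated correlation). Proteases had 5 higher and 1 lower of 16 (8 and 1 adjusted over the list alone, median 0.65, adjusted p = 0.00092, and adjusted p = 0.33 with an estimated correlation) and cytokines 6 higher of 13 (6 adjusted over the list alone, median 0.63, adjusted p = 0.0092, and adjusted p = 0.38 with an estimated correlation). Muscle differentiation genes had 4 of 15 higher (4 adjusted over the list alone, median 0.55, adjusted p = 0.0019, and adjusted p = 0.38 with an estimated correlation). MHC class I genes, with 5 of 11 higher (5 adjusted over the list alone, median 0.64, adjusted p = 0.028, and adjusted p = 0.38 with an estimated correlation), lost the call without FE8 treated replicate 2 (adjusted p = 0.14).

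By fry, cholesterol synthesis, proteases and epithelial genes were called in the averaged effect (adjusted p = 0.046 for each). The averaged count was 264 and 318 without FE8 treated replicates 1 and 2, and 1161 without 208F treated replicate 1. In the DNA methylation machinery list, too few genes were measured for a test, and Dnmt1, the maintenance methyltransferase, stood at -0.17 ± 0.20 and the deacetylase Hdac2 at 0.15 ± 0.25. Genes reported as silenced by RAS were not called for the drug by camera. Their median was 0.17 in 208F (adjusted p = 0.94), 0.68 in FE8 (adjusted p = 0.29) and 0.55 averaged (adjusted p = 0.41). In FE8 and averaged, 1 of 6 was higher and 1 lower. Adjusted over the list alone, 1 was higher and 1 lower in FE8, and 4 were higher and 1 lower averaged.

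**Figure D2:**
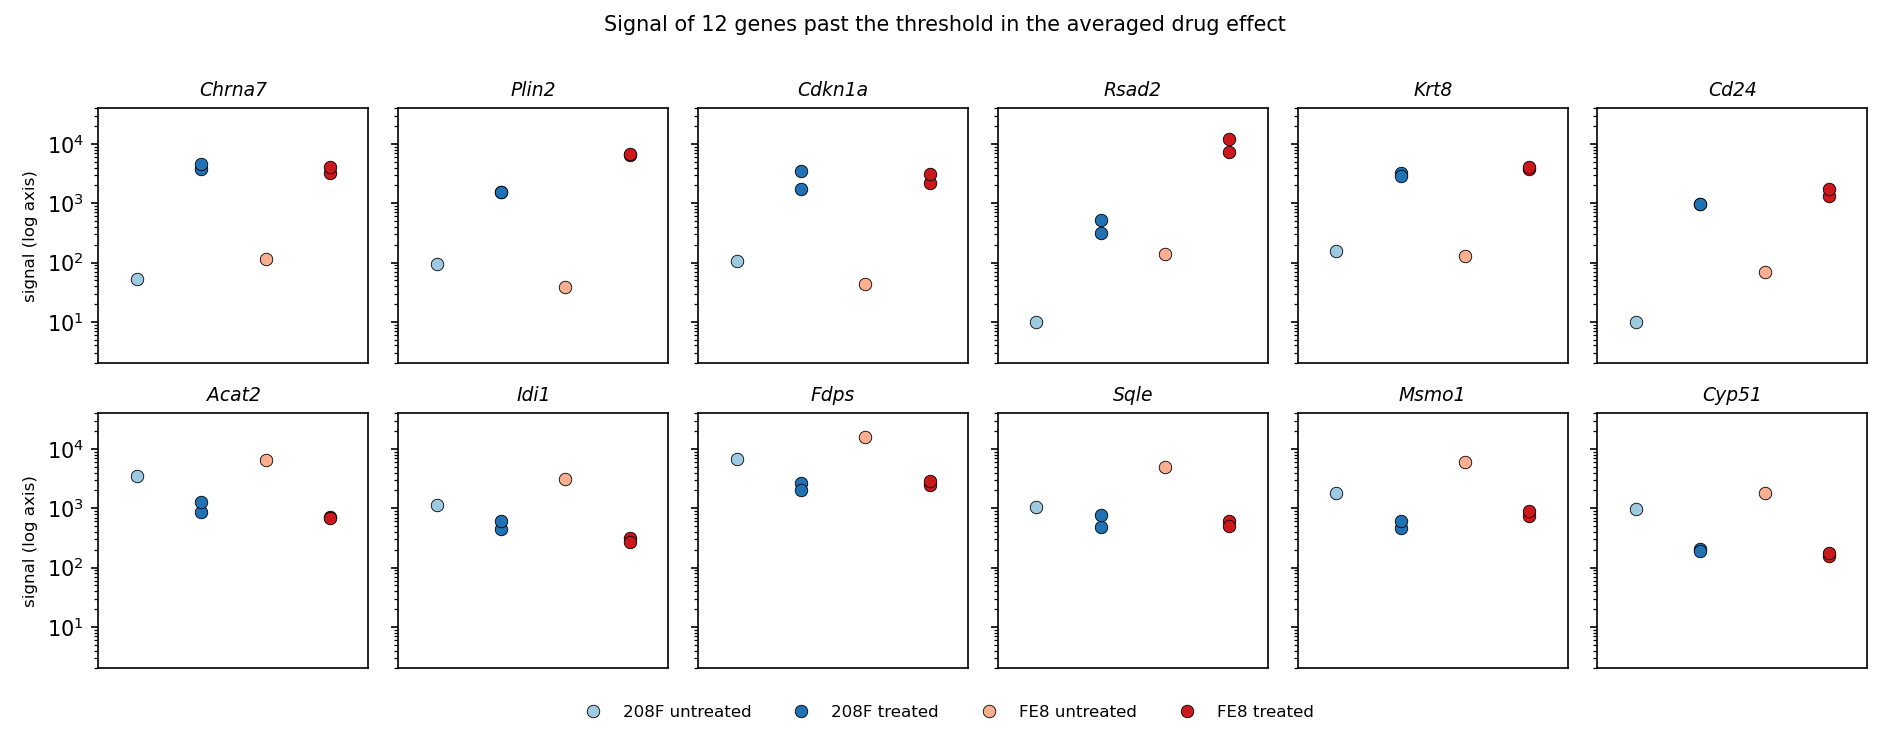
Signal per array (log axis) of 12 genes past the threshold in the averaged drug effect, with 1 point per array in 4 groups, untreated and treated 208F and FE8. Plin2 went from 96 and 38 in the untreated arrays to between 1551 and 6738 in the treated ones, while Acat2 went from 3568 and 6403 to between 698 and 1263.

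The drug effects in the lines, which share no array, correlated across probe sets with Pearson's r = 0.628 and Spearman's rho = 0.570, against 0.004 on average in simulated data without effects. Simulated arrays had independent errors, so a value near 0 was built in. In the data, differences between treated replicates 1 and 2 correlated across probe sets between the lines with r = 0.319. The main fit had no term for this shared part. Both lines called 94 probe sets higher, against 8.8 for independent lists, and 31 lower, against 2.4, and 0 in opposite directions. The sign was shared by 71.0%. The agreement of aza effects was 0.559 without 208F treated replicate 1. Under the 2-fold rule, 238 probe sets were higher and 106 lower in both treated 208F arrays, and 319 were higher and 158 lower in both treated FE8 arrays, against about 10 for each in simulated data (10.51, 10.31, 9.90 and 10.07). Between treated duplicates, 246 probe sets in 208F and 152 in FE8 were at least 2-fold apart, against 116.5 and 114.75 in simulated data. The simulated spread was thus smaller than the measured one, most of all in 208F, and the simulated counts above are too low to that extent.

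**Figure D3:**
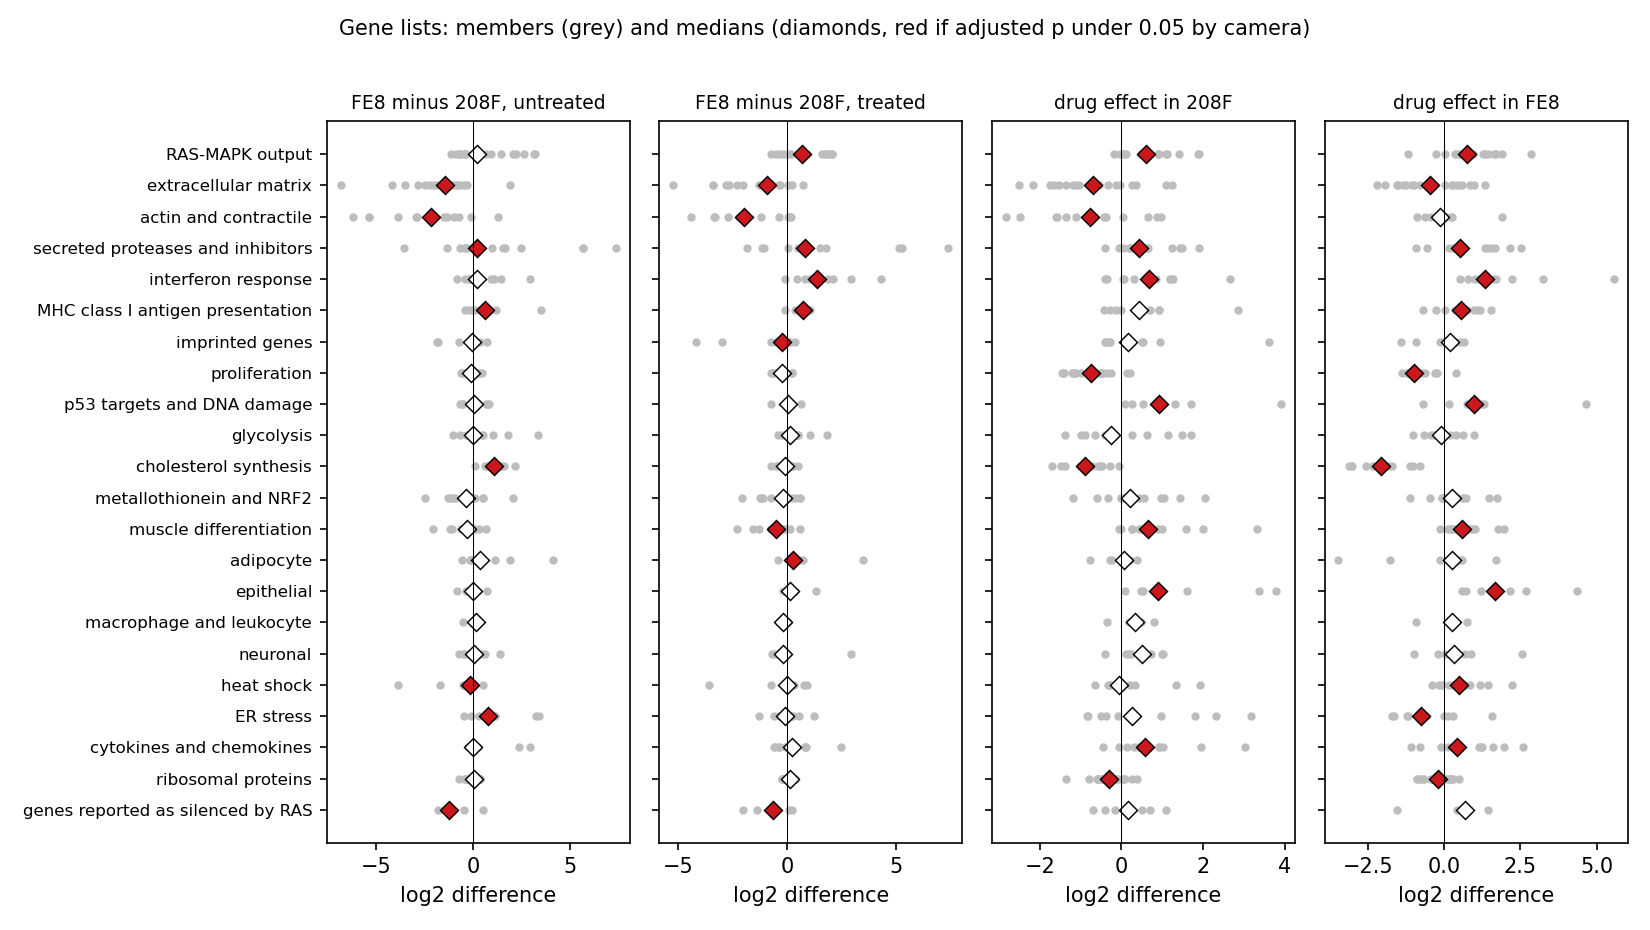
Log2 difference (x axis) of the measured members (grey points) and the median (diamond) of 22 gene lists for the line comparison without and with the drug and for the drug effect in 208F and in FE8; red diamonds passed camera at a preset correlation. Cholesterol synthesis genes stand at a median of 1.08 and -0.11 in the line panels and at -0.90 and -2.09 in the drug panels, and no list passed with an estimated correlation.

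The difference between the drug effects (FE8 minus 208F) asked which genes responded differently in FE8 than in 208F. Plin2 rose more in FE8, by 2.69 ± 0.39 (adjusted p = 0.038), while its second probe set stood at 0.94 and did not pass. The difference was -3.19 ± 0.41 for Ocm, which rose in both lines and less in FE8, and -2.80 ± 0.39 for Ptprn, which rose in 208F only (adjusted p = 0.038 for both). Ptprn went from 35 to 527 and 595 in 208F and from 3277 to 3016 and 2888 in FE8. These 3 probe sets were the only ones past the threshold, and 364 had an unadjusted p under 0.05, against 240.9 by chance. With a term for replicate number 0 passed. All 3 calls were lost without FE8 treated replicate 1 (adjusted p = 0.45 for each) and without replicate 2 (adjusted p = 0.48 for each), with their signs kept.

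Genes next in order did not pass. H19 stood at -3.43 ± 0.53 and Trib3 at -3.20 ± 0.51 (adjusted p = 0.051 for both), Fabp5 at 2.74 ± 0.44 (adjusted p = 0.051), and Scd at -3.50 ± 0.59, the Notch target Hes1 at 2.77 ± 0.49, Egr1 at 2.31 ± 0.41, Aqp8 at 3.27 ± 0.54, Psmb8 at -2.43 ± 0.44 and Col1a1 at 2.14 ± 0.39 (adjusted p = 0.055 for each).

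Although no member passed alone, 5 lists differed as groups by camera. Cholesterol synthesis genes fell further in FE8 (median -1.15, adjusted p = 9.2e-11, 8 lower adjusted over the list alone, and adjusted p = 0.58 with an estimated correlation), with Sqle at -2.30 ± 0.46 and Idi1 at -2.11 ± 0.44. ER stress genes were lower (median -0.87, adjusted p = 7.1e-08, 4 lower adjusted over the list alone, and adjusted p = 0.58 with an estimated correlation), with Trib3 and Ddit3 at -2.04 ± 0.38 largest. For Trib3 the difference is a rise in 208F (143, then 1302 and 2524) without a fall in FE8 (2111, then 2178 and 1996). Interferon genes were higher (median 0.97, adjusted p = 2.6e-07, 2 higher adjusted over the list alone, and adjusted p = 0.76 with an estimated correlation), with Rsad2 at 2.89 ± 0.54. Actin and contractile genes were higher (median 1.03, adjusted p = 0.00083, 5 higher and 1 lower adjusted over the list alone, and adjusted p = 0.58 with an estimated correlation), Myl9 standing at 2.69 ± 0.51. In untreated FE8, Myl9, Tagln and Acta2 had signals of 43, 24 and 108, near or below the pseudocount of 64, and had little room to fall. For these genes the difference rests on the fall in 208F, where the beta-actin ratio of 5' to 3' signal also fell (0.824 to 0.529 and 0.456), unlike in FE8 (0.351 to 0.405 and 0.384). The GAPDH ratio rose in both lines. Heat shock genes were higher (median 0.39, adjusted p = 0.03, 0 adjusted over the list alone, and adjusted p = 0.98 with an estimated correlation), a call lost without 208F treated replicate 2 (adjusted p = 0.14) and without FE8 treated replicate 2 (adjusted p = 0.22).

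By fry no list was called. The count of probe sets was 0 without either FE8 treated replicate, 206 and 99 without 208F treated replicates 1 and 2, 0 after quantile normalization and 17 with 1 probe set per gene.

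The class the design looks for is genes that were lower in untreated FE8 and raised by the drug in FE8. It held 23 probe sets (18 named genes), against 6.9 expected if the calls of the comparisons were independent. Simulated data without effects gave at most 1, but make almost no calls in either comparison. Cryab was at -3.88 ± 0.36 in FE8 against 208F and rose by 2.23 ± 0.31 with the drug. Cald1 was at -3.85 ± 0.39 and rose by 1.90 ± 0.34, Mmp2 at -3.54 ± 0.37 and rose by 2.16 ± 0.32, and Gas6, the ligand of the AXL receptor, at -3.54 ± 0.37 and rose by 1.57 ± 0.32. The second probe set of Gas6 was at -0.55 in untreated FE8 and did not pass. Hes1 was at -2.63 ± 0.40 and rose by 3.05 ± 0.34, from a signal of 12 to 594 and 536, with 406 in untreated 208F.

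Other named members were Fabp5, the thioredoxin inhibitor Txnip (-2.66 ± 0.33 and 2.88 ± 0.28), the latent TGF-beta binding protein Ltbp2, the small GTPase Rhob, the transcription factor Cebpb, the activin antagonist Fst and Myod1 (-2.09 ± 0.40 and 1.78 ± 0.35). Cebpb is in the class by 1 probe set (292 in untreated 208F, 54 in untreated FE8), while its brightest probe set read 1075 and 1547, in the other direction. The remaining genes of the class, listed here after their values were seen, were Sdc1, Sdc4, Plpp1, Fat1, Ptms and Dapk3. Of the 23 probe sets, 11 were still lower in treated FE8 than in treated 208F past the threshold, and the other 12 had a median difference of -0.08. The drug also raised 7 of the 23 in 208F, where the median effect of the class was 0.31, against 1.88 in FE8.

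The mirrored class, higher in FE8 and lowered by the drug, held 19 probe sets (15 named genes), against 4.6 expected for independent calls. Chosen after their values were seen, its genes include Scd, Sult1b1, Slc6a15 and the cholesterol synthesis genes Sqle, Idi1, Msmo1, Fdft1, Fdps and Cyp51. Under the 2-fold rule the classes held 47 and 43 probe sets, against 19.6 and 10.4 expected for independent calls and 3.500 and 3.750 in simulated data without effects. Both steps use the single untreated FE8 array. The classes held 4 and 2 probe sets without either FE8 treated replicate, 65 and 79 without 208F treated replicate 1, 63 and 76 without its replicate 2, and 14 and 7 after quantile normalization.

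**Figure D4:**
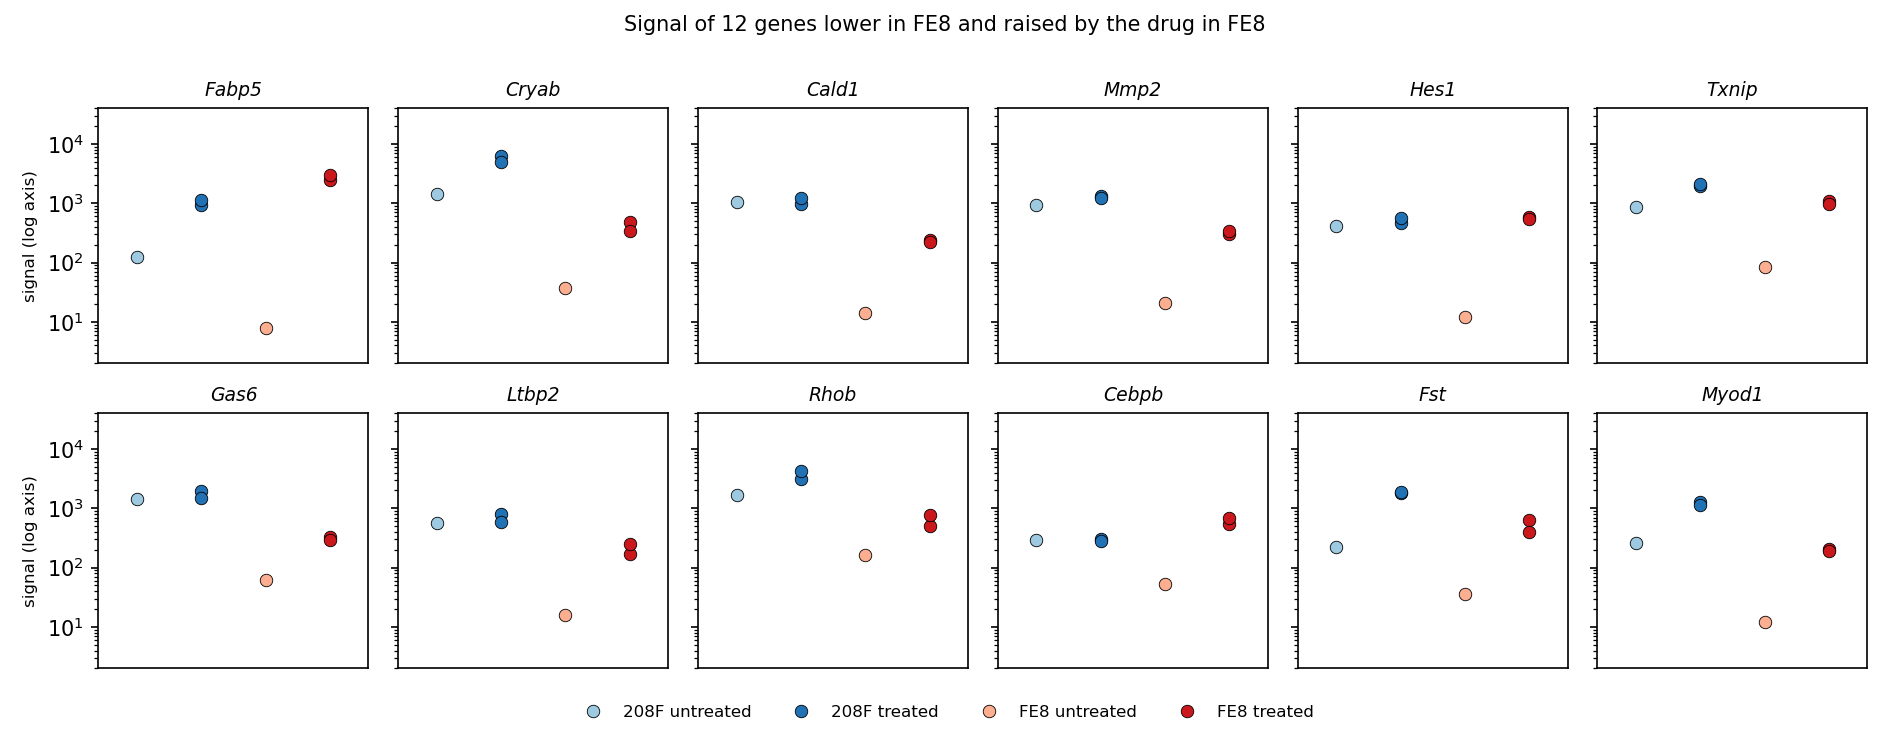
Signal per array (log axis) of the 12 named genes of the class lower in FE8 and raised by the drug in FE8, with 1 point per array in 4 groups. Cryab stands at 37 in untreated FE8, 490 and 341 in treated FE8, and at 1420 or above in the 208F arrays.

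Clusterin (Clu, probe set M64733mRNA_s_at), a secreted chaperone known from work on these lines, had signals of 5639 in untreated 208F, 11176 and 7531 in treated 208F, 2136 in untreated FE8, and 3799 and 3293 in treated FE8. It was lower in FE8 at -1.37 ± 0.35 without the drug (adjusted p = 0.044) and at -1.36 ± 0.25 with it (adjusted p = 0.0057). The drug effect was 0.70 ± 0.30 in 208F (adjusted p = 0.26), 0.71 ± 0.30 in FE8 (adjusted p = 0.2) and 0.70 ± 0.21 averaged (adjusted p = 0.048), and the effects in the lines differed by 0.01 ± 0.43 (adjusted p = 1). The averaged call was lost under 8 of the alternatives, including median centring (0.57, adjusted p = 0.18). The untreated line call was lost under 7, including quantile normalization (adjusted p = 0.051), and the treated one without either FE8 treated replicate (adjusted p = 0.14 and 0.23).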

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

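Among the tests in this part, the comparison of partner probe sets was chosen before its result was seen, and the others were chosen after.

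Results were singled out where the drug effect in FE8 differed from that in 208F by a test of the difference itself. They were 3 genes, Plin2 at 2.69, Ocm at -3.19 and Ptprn at -2.80, each with adjusted p = 0.038. All 3 calls were lost after quantile normalization (adjusted p = 0.11), without either FE8 treated replicate (0.45 and 0.48) and in 3 further settings. As groups they were the lists of actin and contractile genes (median 1.03), interferon response (0.97), cholesterol synthesis (-1.15), heat shock (0.39) and ER stress (-0.87). None of the lists passed with an estimated correlation, and leading actin genes were near the floor in FE8.

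A further pair of results came from control probe sets, which were left out of the tests. In FE8 the probe set for 5S ribosomal RNA had a mean treated signal 3.74 times the untreated one (153, then 623 and 520), against 141, then 135 and 240 in 208F. For the 5' probe set of hexokinase the ratio was 2.38 (32, then 75 and 77, with 82, 82 and 64 in 208F), but these signals lie near the floor and give no measured fold.

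The first pattern weighed is that the drug effect was shared by the lines. If it came from chip lot or scan acting on single probe sets, other probe sets of the called genes would follow at about the rate of random genes, 50.8%. Of 152 called genes with another probe set from another accession, 141 had it move the same way, 92.8% (95% exact binomial interval 87.4 to 96.3), with 53 past the threshold. This argues against such an effect on single probe sets for most of these genes. Random partners were not matched for signal, so a lot or scan effect that depends on signal level was not excluded. The 10th percentile of signal was 49 and 48 in the untreated arrays and between 65 and 86 in the treated ones. Differences between sessions in culture, RNA or handling would reach all probe sets of a gene in both lines, and the correlation of 0.628 between the effects is what both they and the drug would give. The data cannot tell these apart.

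The second pattern is the fall of cholesterol synthesis genes, and in FE8 of ER stress genes, whose median there was -0.76 with an interval that includes 0 (-1.23 to 0.11). If the untreated FE8 array alone had been high, 208F would show no fall, but its median was -0.90 (95% bootstrap interval -1.02 to -0.52). Bootstrap intervals in this paragraph resample genes, not arrays, and leave out the error of the single untreated 208F array. Within that limit, the 208F values argue against a high untreated FE8 array alone for the shared part of the fall. The further fall in FE8, by -1.15, rests on that array, in which the genes were higher than in untreated 208F (median 1.08), and was not separated from it. A session difference would also give the averaged fall of -1.52 (-1.86 to -1.16), so drug and session stay open. For ER stress genes the 208F median of 0.25 (-0.51 to 1.80) does not decide whether the untreated FE8 array was high, and the line medians of 0.78 untreated and -0.11 (-0.36 to 0.28) treated are what a high array would give.

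The third pattern is the class of genes lower in FE8 and raised by the drug, where a low signal in the single untreated FE8 array would produce both steps. Of 23 probe sets, 11 were also lower in FE8 among the treated arrays, which do not include that array. This argues against a low control as the source of their lower signal, while their rise still rests on that array and stays open. The other 12 had a median treated difference of -0.08, which decides nothing, since members lower among the treated arrays had been taken out. The covariance of the untreated line effect and the FE8 drug effect was -0.124, against -0.092 in simulated data that share the control. The simulated spread was smaller than the measured one. A shared control alone gives a negative covariance of the size of the variance per array, and the mean residual variance was 0.114. Most of this covariance may therefore come from the shared array. How much of the class does was not settled, and methylation was not measured here.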

How the results depend on the processing

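No call of the report reversed its sign under any alternative that was run for it. Gene lists were run only with value + 1, quantile normalization, a term for replicate number, arrays left out, an estimated correlation and fry. Leaving out replicates for the gene lists and for the correlations of effects was chosen after seeing the data. Between 124 and 133 values of named genes, called or not, kept their side of the threshold under each setting, and 110 did with 1 probe set per gene, where fewer were measured. Where no reason is given, the cause was not tested.

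After quantile normalization, 165 probe sets passed for the 208F drug effect, 258 for FE8, 0 for the difference, and 14 and 7 in the classes lower in FE8 and raised, and higher and lowered. The count for the difference was 13 with value + 1, 6 with the 30th percentile, 0 without the lowest 30%, 9 with median centring, 0 without an intensity trend, 17 with 1 probe set per gene, where fewer were tested, and 0 with a term for replicate number. The 3 genes called there kept their sign, with adjusted p from 0.053 to 0.48 where they were lost.

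Counts under the fold rule depend on the pseudocount and fold by construction. With value + 1 the class lower in FE8 and raised held 194, and 467 were higher in 208F and 566 in FE8. With the 30th percentile these were 18, 124 and 179, and the class by the test held 14. At 1.5-fold the class held 192, with 581 higher and 316 lower in 208F and 677 and 459 in FE8. At 3-fold it held 9, with 106 and 19 in 208F and 133 and 42 in FE8.

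With an estimated correlation, 0 lists were called in each of the 6 comparisons. With its 2 degrees of freedom that test could pass few lists, so this count says little about correlation. With fry, 0 were called for 208F, 0 for FE8, 3 averaged, 0 for the difference, 2 untreated and 2 treated. With a term for replicate number, 5 were called in the untreated line comparison, against 8 in the main fit, and 9 list calls were lost over all comparisons. After quantile normalization the ribosomal list lost its calls (adjusted p = 0.072, 0.32 and 0.11 for 208F, FE8 and averaged) and heat shock its call for the difference (0.052).

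Leaving out an array gave fewer arrays for the error, and the count moved with the pair of duplicates left to estimate it. Counts without FE8 treated replicates 1 and 2 and without 208F treated replicates 1 and 2 were 75, 78, 663 and 416 for the 208F drug effect. In the same order they were 76, 77, 783 and 779 for FE8, 264, 318, 1161 and 1046 averaged, and 0, 0, 206 and 99 for the difference. For the lines they were 109, 113, 541 and 536 untreated, and 136, 96, 491 and 530 treated. The class lower in FE8 and raised held 4, 4, 65 and 63, and the mirrored class 2, 2, 79 and 76.

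Under the fold rule without an array, 238 to 504 were higher and 106 to 207 lower in 208F, 319 to 513 higher and 158 to 315 lower in FE8, and the class held 47 to 65. The low ends are the main counts, which do not use the arrays of the other line. Without an array of the same line the rule asks for a single treated array, so its count cannot fall. These ranges therefore do not test the rule. Lists called ranged from 12 to 13 for 208F, 10 to 14 for FE8, 12 to 14 averaged, 4 to 7 for the difference, 7 to 9 untreated and 8 to 10 treated.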

Other observations

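Some lists named in the plan are given here as values. Imprinted genes had a treated line median of -0.25 (H19 at -4.16 and the adaptor Grb10 at -2.96, 2 of 10 lower, 2 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.56 with an estimated correlation). Without 208F treated replicate 1 its adjusted p was 0.06 and without FE8 treated replicate 2 it was 0.072. Untreated, the median was -0.06 with adjusted p = 0.17. H19 rose in 208F by 3.62 ± 0.38 and stood at 0.19 in FE8, where Grb10 fell by -1.41 ± 0.32.

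Adipocyte genes were called higher in treated FE8 (median 0.29, adjusted p = 0.047, and adjusted p = 0.34 with an estimated correlation), with 1 of 8 past the threshold, Fabp4, and 1 adjusted over the list alone. The adjusted p was 0.06 without 208F treated replicate 1, 0.11 without replicate 2 and 0.097 without FE8 treated replicate 1. In the FE8 drug effect the median was 0.25 and the mean -0.27, with Scd and the fatty acid synthase Fasn (-1.79) lower and Fabp4 (1.69) higher.

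Heat shock genes were called higher with the drug in FE8 (2 of 10, Cryab and Hsph1 at 1.44, 3 adjusted over the list alone, median 0.49, adjusted p = 0.029, and adjusted p = 0.58 with an estimated correlation) and lower in untreated FE8 (2 of 10, Cryab and Hspb1 at -1.71, 2 adjusted over the list alone, median -0.18, adjusted p = 0.04, and adjusted p = 0.63 with an estimated correlation). Without FE8 treated replicate 2 the adjusted p was 0.17 and 0.074, and without replicate 1 the untreated one was 0.074.

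Ribosomal protein genes had small drug effects. The median was -0.30 in 208F (0 of 30 past the threshold by limma, 0 adjusted over the list alone, adjusted p = 0.0005, and adjusted p = 0.44 with an estimated correlation) and -0.20 in FE8 (0 of 30, 0 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.58 with an estimated correlation). Averaged it was -0.27 (4 of 30 lower, among them Rpl17 at -1.01, 1 adjusted over the list alone, adjusted p = 0.0017, and adjusted p = 0.42 with an estimated correlation). After quantile normalization the adjusted p was 0.072, 0.32 and 0.11, and without FE8 treated replicate 1 the FE8 one was 0.26.

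Lists called in no comparison were neuronal genes (averaged median 0.29, adjusted p = 0.22), where Th rose in FE8 by 2.54 ± 0.33, glycolysis (-0.22, adjusted p = 0.37), metallothionein and NRF2 targets (0.19, adjusted p = 0.22), where the quinone reductase Nqo1 rose by 1.59 ± 0.19 on average, and macrophage genes (0.37, adjusted p = 0.77). In the endothelial list, with too few measured genes for a test, the receptor Flt1 rose in FE8 by 1.73 ± 0.36.

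For the hypotheses below, the test of narrowing was chosen before its result was seen and that of imprinted genes after. The first was that the drug narrows the difference between the lines. The slope of treated on untreated line differences was 0.53. Corrected for the error of the untreated ones it was 0.80 (95% bootstrap interval 0.75 to 0.85, resampling probe sets and not arrays). Before rounding, the corrected slope lay just under the bound set beforehand. The question was nonetheless left open, a judgement made after the result was seen, because the spread of the lone controls was not measured. A control variance of 0.159 per array, 1.40 times the mean residual variance of 0.114, would bring the slope to 1.

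The second hypothesis was that imprinted genes as a list rise with the drug. The averaged median was 0.18 over 10 genes (95% bootstrap interval -0.27 to 0.53, resampling genes, and adjusted p = 0.83 by camera), against 0.106 for all probe sets. Members went both ways, H19 at 1.90 and Grb10 at -0.85, and the question stays open.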
